A study of Camelina sativa with 41 samples.

How the data were processed

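Seeds of Camelina sativa (cultivar Suneson) were collected at 5, 8 and 11 DPA with 3 biological replicates per age, per the labels, and each library was sequenced in 2 runs. RNA libraries were made with a stranded messenger RNA kit, per the labels' protocols. DAP-seq used amplified, and therefore unmethylated, leaf DNA and 22 factors fused to a Halo tag, per the labels' protocols. The series text speaks of duplicates for DAP-seq; whether they were pooled before peaks were called is not given in the sources used here.

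The count table holds whole-number counts per gene that the authors deposited, with a column per run. The submitters' processing notes name bcl2fastq 2.20.0, FastQC, Trimmomatic, Bowtie2 2.3.4.1 and HISAT2 2.0.4 without saying what each was used for. The counting tool, its use of strand, its treatment of reads that match several places, the annotation and the genome build are not given in the sources used here. The genome holds 3 sets of similar chromosomes, so counts of near-identical copies may be shared or lost and are uncertain. The gene length (another deposited column, in bases, per the file headers) was not used in any test. The peak lists are in narrowPeak layout and are named as events of the GEM peak caller by the authors. Each peak has the authors' score (at most 1000), a signal that the authors give per peak in no stated unit, and −log10 of p and q as the authors list them; −log10 of q was at least 2 in every list. Peaks were 201 bp wide except for 1 in the list of Csa04g023980 and 1 in that of Csa13g019570, and the authors' position at the centre was taken as the summit. The score, signal and −log10 values were used only to describe or rank peaks within a list. The score was at its cap for 10.2% to 95.6% of the peaks of a list of 50 or more, so equal scores were ranked by signal.

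Counts of the 2 runs of a replicate were summed to 1 library, as planned, except for 5 DPA replicate 1: its resequenced column equals that of 5 DPA replicate 2, and was counted once, with the replicate whose first run it matched. Run pairs of the other replicates differed by a chi-square of 1.33 to 1.45 per degree of freedom over genes with at least 20 summed counts. Replicates of an age differed by more than runs (1.96 to 21.2), so each was kept as a sample of its own. Library totals were 15659011 counts for 5 DPA replicate 1 and 38268473 to 46863553 for the rest, which puts the floor of 3 counts at 0.192 CPM and at 0.0640 to 0.0784 CPM. Over the 3 libraries of an age it is 0.0303, 0.0247 and 0.0224 CPM at 5, 8 and 11 DPA. Intervals and floors cover counting error only.

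Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM, filterByExpr, glmQLFit and glmQLFTest, all 3 ages in 1 fit, no other term, Benjamini-Hochberg adjusted p under 0.05, no fold threshold). The filter left 63017 genes, and 7998 had no count in any library. CPM scale counts to each library's total. Standard errors are the log2 change divided by the root of the F statistic. The set of factors was tested with camera (preset correlation 0.01, and estimated) from limma 3.58.1. Counts were simulated with 200 changed genes for 8 versus 5 DPA, all with a mean count of at least 50 (62207 genes run). Of these, 7.46% of 1.5-fold, 52.2% of 2-fold and 89.4% of 4-fold changes were found, with 1 false call. In the data 22436 genes were called in this comparison. The adjustment is stricter where fewer genes change, so these shares are not those found in the data. A summit was called shared when a summit of the other list lay within 100 bp. The share was set against the same summits moved at random by 5000 to 20000 bp (100 draws, lists of at least 50 peaks), and a fold was given where moved summits shared at least 1 on average. On simulated lists of positions drawn at random, with 30% of summits planted, 30.4% were found, and unplanted lists gave 0.942-fold. Lists whose peaks gather in the same regions were not simulated. Peaks and figures used Python, NumPy, SciPy, pandas and Matplotlib.

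The groups, tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined. The rule takes, for 8 versus 5 and 11 versus 8 DPA, the largest log2 changes among called genes with a mean of at least 10 CPM over all libraries and no overlap between the replicates compared. As 0 of the gene IDs matched a name or identifier among the 98741 genes of the reference table, only the top 2 of each direction are printed. The alternatives tried were DESeq2 1.42.0 (its test, and its size factors in edgeR), no low-count filter, only the 2 ages compared, a 2-fold threshold, the replicate number as a block, each replicate left out, and the first run alone. For peaks they were 50 and 200 bp and the higher-scoring 50% of each list. Runs summed as deposited, the first run alone for the pairs of ages, the test of the factors as a set and of the difference between steps, and the comparison of chromosome groups' counts were added after seeing the data.

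The planned tests of gene lists need names, those of sequence words at summits need a genome, and those of genes near summits need gene positions of the build used. None of these was used here, so those tests were not run, and peaks are not tied to genes.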

Results

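Camelina (Camelina sativa, an oilseed of the mustard family with a hexaploid genome) was examined in 2 ways: by sequencing of messenger RNA from seeds of the cultivar Suneson at 5, 8 and 11 days post-anthesis (DPA, days after the flower opens), and by DNA affinity purification sequencing (DAP-seq) of transcription factors. In DAP-seq a tagged protein made outside the plant is mixed with fragments of genomic DNA, and the fragments it holds are sequenced. The DNA here came from leaves and had been amplified, which removes methylation. Each age had 3 biological replicates, so 9 libraries were compared. The labels name 22 factors by gene ID, and peak lists of 20 of them were analysed. The lists of Csa17g034220 and Csa19g036630 were not analysed here. The series title gives the regulation of lipid metabolism as the subject.

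The count table held 89418 genes, of which 85274 carried a chromosome number in their ID. Library totals ran from 15659011 counts (5 DPA replicate 1) to 46863553 (11 DPA replicate 1), and the other 7 libraries lay between 38268473 and 45901631. For 5 DPA replicate 1 only the first sequencing run was used. Its resequenced column was identical to that of 5 DPA replicate 2 for all 89418 genes, and differed from the first run of replicate 1 by a chi-square of 9.39 per degree of freedom, against 1.34 for the first run of replicate 2. That column was therefore counted once, with replicate 2. The files do not pair gene IDs with names, so genes are given by ID.

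Age separated the seed libraries. The first principal component of log2 CPM (counts scaled to a common library total) took 73.5% of the variance and ordered the libraries by age. The second took 14.3% and set the 8 DPA libraries apart from both other ages. Among replicates, 8 DPA replicates 1 and 2 were closest (chi-square per degree of freedom 1.96 between first runs), and 11 DPA replicate 1 stood farthest from the others of its age (21.2 and 17.7).

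**Figure D1:**
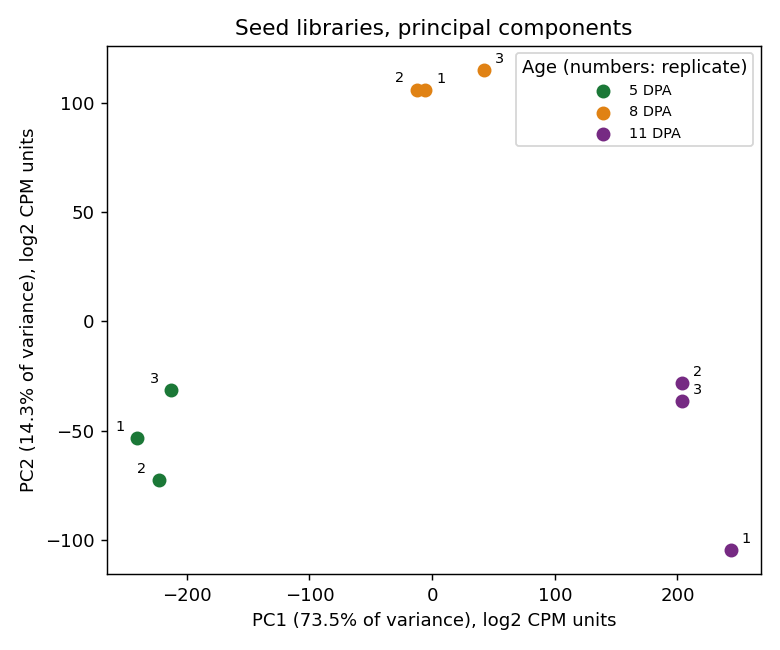
Principal components of the 9 seed libraries on log2 CPM; each point is a library, coloured by age and numbered by replicate. PC1, with 73.5% of the variance, runs from the 5 DPA libraries to the 11 DPA libraries, and the 8 DPA libraries lie at the top of PC2 (14.3%).

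Most of the tested genes changed with age. Of 63017 genes tested, 39124 (62.1%) differed among the 3 ages by edgeR's quasi-likelihood F-test at a Benjamini-Hochberg adjusted p under 0.05. Both steps contributed: 22436 genes changed from 5 to 8 DPA and 25525 from 8 to 11 DPA. The scaling of libraries sets the median change near 0 (log2 -0.0139 and 0.00229), so the balance of rises and falls is not a finding. The 10 most abundant genes of each library held 3.48% ± 0.371 of the counts at 5 DPA, 3.85% ± 0.163 at 8 DPA and 5.34% ± 1.20 at 11 DPA (SD, n = 3 each), with 6.71% in 11 DPA replicate 1.

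From 5 to 8 DPA, 11378 genes rose and 11058 fell, together 35.6% of those tested. The change was at least 2-fold for 5312 of the rising and 5517 of the falling genes. It was at least 8-fold for 1544 and 1278. The largest rises under the rule for named genes were those of Csa19g012260 and Csa06g025120. Csa19g012260 had no count at 5 DPA (a floor of 3 counts over the group, or 0.0303 CPM), 32.2 CPM ± 12.7 at 8 DPA and 255 CPM ± 76.7 at 11 DPA (SD, n = 3), at least 1050-fold higher at 8 DPA (edgeR adjusted p = 2.94e-05); the bound was 633-fold without 5 DPA replicate 2 and 582-fold without 5 DPA replicate 3. Csa06g025120 had 1 count at 5 DPA, 111 CPM ± 27.6 at 8 DPA and 39.9 CPM ± 29.8 at 11 DPA. Its ratio of 8 to 5 DPA was 10900 (95% counting interval 1950 to 430000, edgeR adjusted p = 9.87e-05). It was 6570 without 5 DPA replicate 2 and at least 2010-fold without 5 DPA replicate 3, which held the count.

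The largest falls were those of Csa11g073840 and Csa20g061900. Csa11g073840 had 70.2 CPM ± 100 at 5 DPA and 0.116 CPM ± 0.0802 at 8 DPA, and Csa20g061900 had 62.4 CPM ± 87.3 and 0.155 CPM ± 0.144 (SD, n = 3). Their edgeR adjusted p-values were 0.00143 and 0.00532. Most of the 5 DPA signal was in replicate 2, with 186 CPM of Csa11g073840 and 163 CPM of Csa20g061900 against 7.60 and 17 CPM, and 7.28 and 16.9 CPM, in replicates 1 and 3. Without that library the ratio of 5 to 8 DPA was 126 in place of 714 for Csa11g073840 and 91.8 in place of 468 for Csa20g061900, and both remained called (edgeR adjusted p = 3.94e-05 and 0.000667). The ratios were 1170 and 757 without 5 DPA replicate 3, and 1130 and 755 without 8 DPA replicate 1.

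From 8 to 11 DPA, 13123 genes rose and 12402 fell, 40.5% of those tested. The change was at least 2-fold for 5620 rising and 5542 falling genes. It was at least 8-fold for 921 and 1500. The largest falls were those of Csa11g011130 and Csa09g051690. Csa11g011130 went from 63.7 CPM ± 6.33 at 5 DPA and 9.27 CPM ± 4.19 at 8 DPA to 1 count in the 3 libraries of 11 DPA, a ratio of 8 to 11 DPA of 1260 (counting interval 226 to 50000, edgeR adjusted p = 2.76e-05). That 1 count lay in replicate 1, and without this library the level at 8 DPA was at least 274-fold higher; the ratio was 832 without 11 DPA replicate 2. Csa09g051690 went from 184 CPM ± 54.2 at 5 DPA and 66.8 CPM ± 11.6 at 8 DPA to 0.0957 CPM ± 0.0466 at 11 DPA (SD, n = 3 each; ratio 685, edgeR adjusted p = 1.43e-06).

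The largest rises from 8 to 11 DPA were those of Csa11g070580 and Csa11g017010, neither of which had a count at 8 DPA. Their levels at 11 DPA were at least 3640-fold and 3070-fold higher, with 8 DPA set at the floor of 3 counts over the group (edgeR adjusted p = 0.0111 and 0.0202). Replicate 1 held most of it, with 242 and 208 CPM, against 10.6 and 6.52 CPM of Csa11g070580 and 6.08 and 3.67 CPM of Csa11g017010 in replicates 2 and 3. Without 11 DPA replicate 1 the bounds were 351-fold and 199-fold, and without 8 DPA replicate 2 they were 2310-fold and 1950-fold. The call of Csa11g017010 was lost without 8 DPA replicate 1 or 8 DPA replicate 2 (adjusted p = 0.0533 and 0.0543). Both genes also had counts in 5 DPA replicate 2 (1.66 and 3.46 CPM) and none in the other 5 DPA libraries. With the first run alone the genes named for these 2 steps remained called. Groups with no count then give bounds that follow the number of reads and do not test the rise: at least 538-fold for Csa19g012260, 1840-fold for Csa06g025120 (whose 1 count was in the other run), 1530-fold for Csa11g070580 and 1350-fold for Csa11g017010. The ratio was 380 in place of 714 for Csa11g073840, 553 in place of 1260 for Csa11g011130 and 1280 in place of 685 for Csa09g051690.

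Over the whole span from 5 to 11 DPA, 18808 genes rose and 18351 fell, 59.0% of those tested, and 9546 and 9631 did so at least 2-fold. A group of 23 genes had no count at 5 DPA and a mean of at least 10 CPM at 11 DPA, and 14 showed the reverse. Genes called in both steps mostly kept their direction: 4367 rose in both and 4421 fell in both, against 2369 and 2176 for independent calls. By contrast 1593 rose and then fell and 1443 fell and then rose, against 2239 and 2303. Both steps share the 8 DPA libraries, which enter them with opposite signs, so chance values of these libraries would favour genes that change in opposite directions and not those that keep theirs. Simulated libraries with no change gave 0 genes called in both steps (mean of 5 simulations), which says nothing about direction.

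Most of the 22 assayed factors became more abundant as seeds aged, and none fell at any step by edgeR (0 also at an unadjusted p under 0.05, and 0 by DESeq2). Of these, 20 could be tested; Csa01g013850 and Csa09g088620 had no count in any library. From 5 to 11 DPA 18 rose by edgeR's test adjusted over all genes and 19 when adjusted over the list alone. From 5 to 8 DPA 12 rose (13 over the list alone), and from 8 to 11 DPA 11 rose (12 over the list alone). As a set, the factors rose more than other genes by camera with its preset correlation (adjusted p = 5.02e-06, 1.5e-07 and 1.03e-08 for 8 versus 5, 11 versus 8 and 11 versus 5 DPA). With an estimated correlation the adjusted p was 0.0548 in each of the 3 comparisons. The series title names gene co-expression; where the study picked the factors on these samples, their direction is not independent evidence.

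The timing of the rise differed among factors. The log2 changes of the 2 steps differed for 6 of the 20 factors, by a test added after seeing the data: the first step was the larger for Csa02g060070, Csa18g003140 and Csa04g012470, and the second for Csa08g011090, Csa13g021450 and Csa10g008930. Csa02g060070 went from 0.994 CPM ± 0.153 at 5 DPA to 10.1 CPM ± 1.69 at 8 DPA (log2 change 3.25, SE 0.16, edgeR adjusted p = 2.71e-06) and stood at 9.41 CPM ± 0.795 at 11 DPA. Csa18g003140 likewise went from 2.98 CPM ± 1.75 to 26.3 CPM ± 0.827 (log2 change 3.03, SE 0.30, edgeR adjusted p = 7.07e-05), with 23.1 CPM ± 1.41 at 11 DPA (SD, n = 3 for each). Its log2 change was 3.73 without 5 DPA replicate 3. The change from 8 to 11 DPA passed no threshold for either (adjusted p = 0.891 and 0.762). The second step was below the first by 3.28 (SE 0.24) and 3.15 (SE 0.46) on the log2 scale, with edgeR adjusted p of 5.64e-05 and 0.00173; the latter difference was 3.85 without 5 DPA replicate 3.

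Csa08g011090 and Csa13g021450 rose from 8 to 11 DPA and were not called from 5 to 8 DPA. Csa08g011090 had 6.6 CPM ± 0.891, 6.35 CPM ± 0.324 and 27.9 CPM ± 11.8 at the 3 ages, and Csa13g021450 had 3.41 CPM ± 0.0280, 3.72 CPM ± 0.365 and 18.3 CPM ± 7.16 (SD, n = 3). The log2 changes from 8 to 11 DPA were 2.22 (SE 0.28) and 2.39 (SE 0.26), with edgeR adjusted p of 0.00032 and 0.000146; those from 5 to 8 DPA had adjusted p of 0.810 and 0.850. Csa10g008930 also rose, by 3.95 on the log2 scale from 8 to 11 DPA (SE 0.31, edgeR adjusted p = 3.19e-05). Its counts were low, with 12 at 5 DPA (0.111 CPM), 35 at 8 DPA (0.292 CPM) and 576 at 11 DPA. Its log2 change from 5 to 8 DPA was 1.21, with an edgeR adjusted p of 0.0539 over all genes and 0.0302 over the list alone. The second step exceeded the first by 2.32 (SE 0.50) for Csa08g011090, 2.31 (SE 0.47) for Csa13g021450 and 2.74 (SE 0.67) for Csa10g008930 on the log2 scale, with edgeR adjusted p of 0.0117, 0.00872 and 0.0199. This call was lost for Csa08g011090 without 8 DPA replicate 1 (0.0579). For Csa10g008930 it was lost with the first run alone (difference 1.56, adjusted p = 0.539) and without 5 DPA replicate 2 (0.0890), 8 DPA replicate 2 (0.0815) or 8 DPA replicate 3 (0.0688).

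Csa04g012470 and Csa19g036630 rose in both steps. Csa04g012470 went from 0.236 CPM ± 0.112 to 8.33 CPM ± 1.74 and 52.8 CPM ± 15.5 (SD, n = 3), with log2 changes of 4.99 and 2.75 (edgeR adjusted p = 1.8e-05 and 6.06e-05); the first was 5.6 without 5 DPA replicate 3. Its second step was below the first by 2.23 (SE 0.56, edgeR adjusted p = 0.0216), or by 2.85 without 5 DPA replicate 3, a call lost without 5 DPA replicate 2 (0.0627) or 8 DPA replicate 1 (0.0550) or 3 (0.0749). Csa19g036630 went from 0.335 CPM ± 0.0890 to 2.11 CPM ± 0.837 and 31.5 CPM ± 14.3, with log2 changes of 2.56 and 4.0 (edgeR adjusted p = 0.006 and 7.61e-05). Csa02g073390 had 1 count at 5 DPA, 118 at 8 DPA and 994 at 11 DPA, a ratio of 11 to 5 DPA of 734 (counting interval 131 to 29000), and Csa04g023980 had 2, 35 and 293 counts, a ratio of 108 (29.7 to 897). Single libraries moved these ratios by over 1.5 times, and both rises remained called. The ratio of Csa02g073390 was 443 without 5 DPA replicate 2 and 479 without 11 DPA replicate 1. Without 5 DPA replicate 3, which held the 1 count, or with the first run alone, no count was left at 5 DPA, and only bounds of at least 136-fold and 129-fold can be given. The ratio of Csa04g023980 was 182 without 5 DPA replicate 1 and 60 without 5 DPA replicate 3. Calls at low counts or of small size were less firm. From 5 to 8 DPA the call of Csa04g023980 was lost without 5 DPA replicate 3 (edgeR adjusted p = 0.0522) and that of Csa17g034220 without 5 DPA replicate 2 or 8 DPA replicate 1 or 3 (adjusted p up to 0.0647). That of Csa04g050690 was lost in 8 of 16 alternatives, among them without 5 DPA replicate 2 or 3 or any 8 DPA library (up to 0.113). That of Csa06g051300 was lost in 8 of 15, and was kept only without 5 DPA replicate 3 or 8 DPA replicate 1 among the libraries left out (up to 0.15). From 5 to 11 DPA that of Csa11g037200 was lost in 5 of 16, among them without replicate 2 or 3 of either age (up to 0.0683). Csa13g019570, at 0.292, 0.148 and 0.226 CPM, and Csa19g005080, at 0.271, 0.235 and 0.512 CPM, were not called from 5 to 11 DPA (adjusted p = 0.620 and 0.0703).

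**Figure D2:**
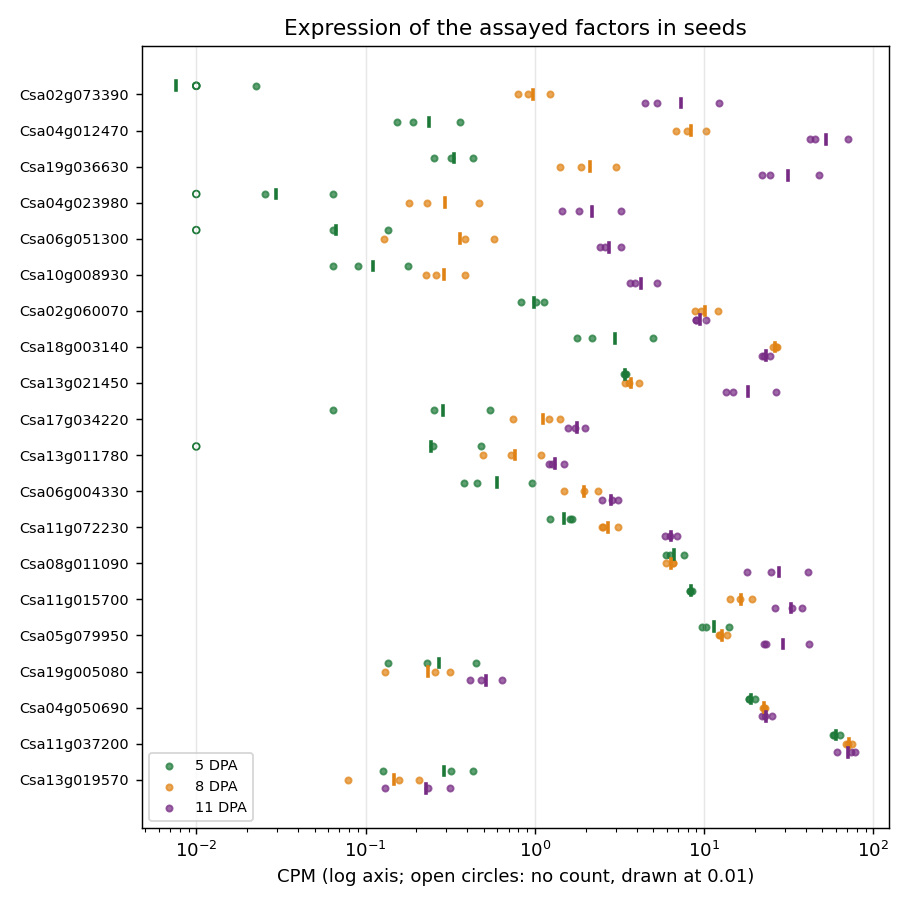
CPM (log axis) of the 20 tested factors in each seed library, ordered by their log2 change from 5 to 11 DPA; points are libraries, short bars the mean of the 3 replicates, and open circles libraries with no count. Csa02g060070 and Csa18g003140 rise from 5 to 8 DPA, while Csa08g011090 and Csa13g021450 rise from 8 to 11 DPA.

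The DAP-seq lists differed widely in length. Together the 20 lists held 717159 peaks, with 13 for Csa19g005080 and 129638 for Csa02g073390. The next longest were those of Csa04g012470 (117085 peaks), Csa13g019570 (98602), Csa06g004330 (92476), Csa01g013850 (79212) and Csa13g011780 (72460). Besides Csa19g005080, the lists of Csa11g037200 (45), Csa11g015700 (211), Csa04g050690 (278), Csa05g079950 (620), Csa18g003140 (1089), Csa02g060070 (1185) and Csa10g008930 (1778) held under 2000 peaks. The remaining lists were those of Csa08g011090 (5259), Csa11g072230 (8083), Csa13g021450 (11761), Csa09g088620 (24765), Csa04g023980 (25141) and Csa06g051300 (47458). The 2 factors with no seed count, Csa01g013850 and Csa09g088620, thus had 79212 and 24765 peaks. Each factor had a single list, so no test between factors was made; a list's length also depends on sequencing depth, which is unknown here.

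Some factors shared many of their sites. The first pairs given here are of lists with 2000 or more peaks. Csa08g011090 shared 3273 of its 5259 summits (62.2%) with Csa13g021450 within 100 bp, 124-fold more than the same summits moved by 5000 to 20000 bp, with a median distance of 1 bp. Csa01g013850 shared 47379 of its 79212 summits (59.8%) with Csa13g019570, 17.9-fold more than moved summits, with a median distance of 0 bp. Moved summits shared 3.35% for this pair, against 0.503% for Csa08g011090 and Csa13g021450, so these folds have unlike upper limits. Csa11g072230 shared 23.3% of its summits with Csa06g051300 (13.9-fold, median distance 36 bp), and Csa09g088620 shared 10.1% with Csa04g023980 (11.5-fold, median distance 4 bp). The authors' signal at shared sites had Spearman's rho of 0.70, 0.52, 0.22 and 0.21 across sites in these 4 pairs (sites are not independent replicates).

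Other pairs shared fewer sites than moved summits did. Csa06g004330 held 1.48% of the summits of Csa13g021450 and 1.56% of those of Csa08g011090, 0.491 and 0.510 times the moved summits, and Csa04g023980 held 0.482% of those of Csa11g072230 (0.578 times). Of 153 pairs of lists with at least 50 peaks, 136 shared more summits than moved ones, 3 fewer and 14 neither, at an adjusted p under 0.05 (permutation by 100 moves, two-sided; the smallest p this allows is 0.0198). Joined over all lists, summits formed 555003 positions, of which 432781 (78.0%) were in a single list and 1211 in 5 or more. Summits were moved to any position, whether or not peaks of any list occur there. An excess over moved summits is therefore not by itself particular to a pair. These tests describe 1 list per factor and were not repeated on a second.

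**Figure D3:**
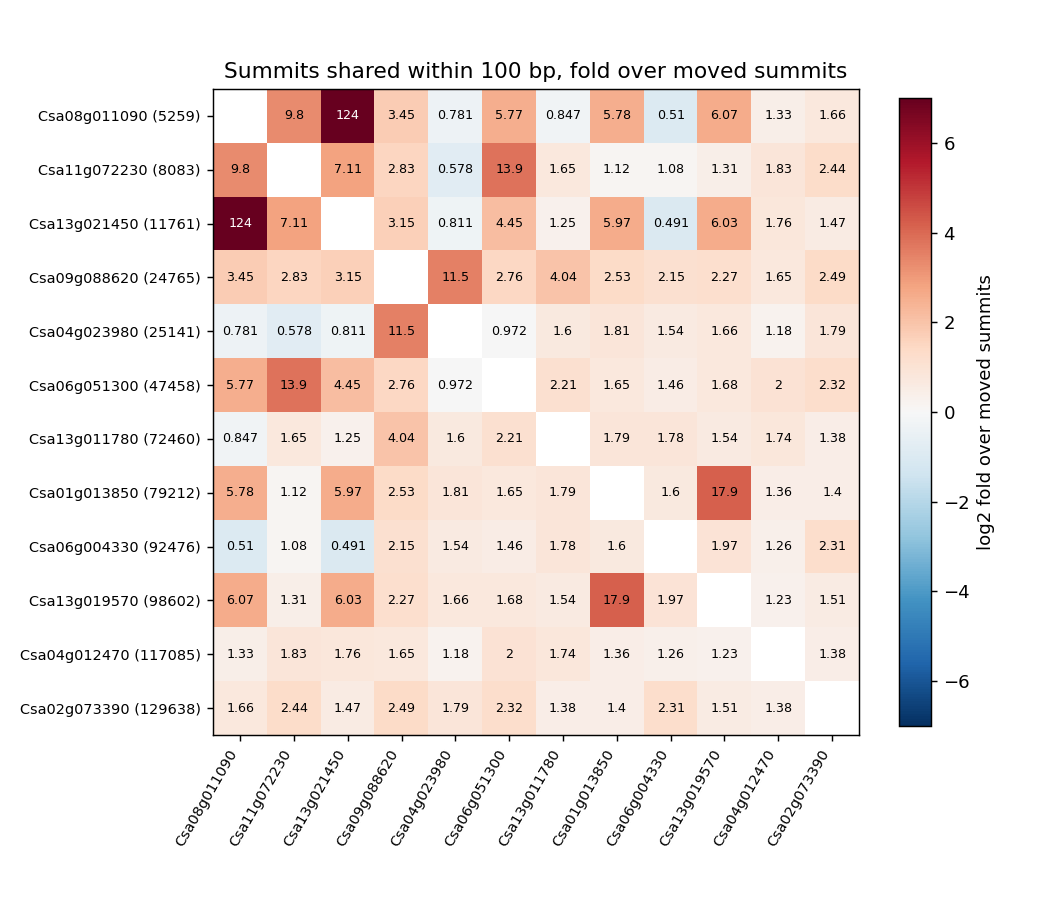
Fold of summits shared within 100 bp over moved summits for the 12 lists of 2000 or more peaks (colour: log2 fold; numbers: fold; list lengths in parentheses). Csa08g011090 with Csa13g021450 (124-fold) and Csa01g013850 with Csa13g019570 (17.9-fold) stand out, and Csa06g004330 shares fewer sites with Csa08g011090 and Csa13g021450 than moved summits do.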

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

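Counts of changed genes moved by under 1.5 times under the alternatives other than the 2-fold threshold, which gave 10829 genes for 8 versus 5 DPA, 11162 for 11 versus 8 DPA and 19177 for 11 versus 5 DPA; it removes small changes by construction. The remaining alternatives gave 18550 to 25453, 20565 to 27530 and 31882 to 39152 genes, and 33118 to 42039 over all ages. The lowest of each came from the first run alone and the highest from the runs summed as deposited, which puts the same column in 2 replicates. Leaving out a replicate gave 16457 to 24447 genes for 8 versus 5 DPA (lowest without 8 DPA replicate 3), 18531 to 26894 for 11 versus 8 DPA (lowest without 8 DPA replicate 2), 34758 to 36823 for 11 versus 5 DPA and 35733 to 37890 over all ages. Factors that rose numbered 9 to 13, 11 to 12 and 17 to 19 when a replicate was left out.

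The replicate block gave 20861, 23941, 35856 and 37254 genes for the same 4 tests. Same-numbered libraries had correlations of -0.068 to 0.18 between their deviations from the age means over 9 pairs, and 2 of 9 libraries correlated best with their own number, so the numbers were not taken to pair samples. Of 68 tests of named genes and factors, 49 were called; 6 of these lost the call and 6 others gained one under some alternative, and none reversed. The cause was not tested.

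The higher-scoring 50% of each list had a median of 4961.5 peaks against 9922, by construction. Pairs sharing more summits than moved ones numbered 133 at 50 bp, 139 at 200 bp and 111 in the higher-scoring 50%, against 136. The alternatives planned for gene lists, sequence words and genes near summits were not run.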

Other observations

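Some tests were chosen after the results they bear on were seen. They concern the genes seen in 5 DPA replicate 2, the shift over most genes of a chromosome group and the other splits. Predictions on the most abundant genes, positions in many lists and shared sites with expression were written before the tests. The comparison of chromosome groups' counts, on which the most abundant genes bear, was itself added after seeing the data.

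The third of 3 sets of similar chromosomes took a growing share of the seed libraries' counts. By the published assignment of Camelina chromosomes to 3 groups, the third group (chromosomes 2, 5, 9, 12, 15, 17 and 20) held 37.5% ± 0.0505 of the counts on chromosomes at 5 DPA, 37.9% ± 0.0171 at 8 DPA and 39.2% ± 0.274 at 11 DPA (SD, n = 3). The rise from 5 to 11 DPA was 1.76 points (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 libraries allow). A shift over most of its genes is argued against, since their median log2 change was not above that of the other groups' genes (difference -0.0139) and 30.1% of them rose, against 29.6% and 30.3%. Without the 100 most abundant genes, 47 of which lie in the third group, the share did not rise. It was lower at 11 DPA than at 5 DPA (-0.329 points, SD 0.171, exact permutation p = 0.1, two-sided). A few very abundant genes may therefore account for the rise.

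Genes next to each other in ID order changed a little alike from 5 to 11 DPA: across 61655 pairs of tested neighbours the correlation of log2 changes was 0.10, against 0.034 for genes 2 places apart and 0.0044 for genes 10 places apart. These are correlations across genes, which are not independent replicates.

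A few genes that are silent at 8 DPA and seen at 11 DPA also appear in 5 DPA replicate 2. The 7 genes with at least 5 CPM at 11 DPA and no count at 8 DPA had 275 counts there, against 2 and 10 in 5 DPA replicates 1 and 3. The pattern rests on 3 of them, which held 267 of the 275 (136 for Csa11g017010 and 65 for Csa11g070580); 1 had none. A fixed share of RNA or reads with the profile of any of the 3 libraries of 11 DPA, or of their sum, is argued against. The counts departed from each of these profiles by at least 75.8 per degree of freedom (chi-square, which allows for counting error only). The 11 DPA libraries differed among themselves in these genes, with 208, 6.08 and 3.67 CPM of Csa11g017010 in replicates 1, 2 and 3. The test therefore does not cover 11 DPA seeds with another profile. Reads that entered in 1 run are argued against as well, since the share of these counts differed by 1.07 times between the runs. Whether some seeds of that sample were further along stays open. Genes that rose in both steps had a median log2 ratio of 0.0227 to the other 5 DPA libraries, against -0.0831 for replicate 1 and 0.0373 for replicate 3. By this measure replicate 2 as a whole was not further along than replicate 3, which had 10 counts of the 7 genes. RNA of another tissue in the sample could not be tested without gene names.

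The short DAP-seq lists share positions more often than moved summits do. All 15 pairs among the 6 lists with 50 to 2000 peaks shared more summits than moved ones, and 575 of their summits lay within 100 bp of a summit of another short list. These 575 lay near 1.53 of the 12 long lists on average (95% bootstrap interval 1.43 to 1.64), against 0.900 (0.871 to 0.928) for the other 4586. Positions found in many lists whatever the factor may account for part of the sharing, but sharing particular to some pairs could give the same values. Csa18g003140 and Csa10g008930 alone shared 153 summits (73.6-fold). Csa18g003140 also shared 208 summits with the long list of Csa08g011090 (99.5-fold) and 163 with that of Csa13g021450 (34.5-fold). The intervals treat summits as independent, though a shared position counts once in each short list that holds it, so they are too narrow. The lists also differed in their part of shared summits, from 5.0% for Csa05g079950 to 23.2% for Csa11g015700. Factors with like sequence preferences would also share sites, which was not tested without a genome, and the Halo control was not used here.

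A hypothesis that factors with more sites in common are expressed more alike could not be decided. Over 102 pairs of 16 factors, Spearman's rho between overlap fold and the correlation of expression across libraries was 0.13 (permutation p = 0.416, 100000 permutations of the factors). Pearson's r was 0.10, and rho was 0.11 without the pair with the highest of these folds. A p of this size does not show that no relation exists. The fold a pair can reach is lower where moved summits share more, as with long lists. Its ranks may thus partly follow list length. Pairs with no fold, whose moved summits shared under 1 on average, were left out. All of those pairs shared more summits than moved ones, with 23 against 0.08 for Csa11g015700 and Csa04g050690. Most factors also rose with age, and the correlations of expression take in that common rise.

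Other splits of the libraries were compared with the split by age. For the test over all ages, 1 of 40 splits drawn from 280 (the real one) gave as many as 39124 genes and the highest other gave 15057. This is the smallest share that 40 splits allow. Mixing ages also widens the spread within groups, which lowers the counts of the other splits. The real split ranked first, but chance is not excluded by this. For each pair of ages only 10 splits exist, too few for a share under 0.05: the real split gave 22436, 25525 and 37159 genes for 8 versus 5, 11 versus 8 and 11 versus 5 DPA, and the highest other split gave 0 each time, with 1 split as large, the real one.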
